A study of Mus musculus with 12 samples.

How the data were processed

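Gene expression was measured on 12 one-colour arrays with total RNA from naive CD4 T cells of C57BL/6 mice, either WT or transgenic for PP2Ac, the catalytic subunit of protein phosphatase 2A encoded by Ppp2ca. Per the labels, cells were left unstimulated (0 h) or stimulated for 6 h or 24 h. Antibodies against CD3 (0.25 ug/mL) and CD28 (0.5 ug/mL) were added in solution to plates coated with a goat antibody against hamster immunoglobulin. RNA was extracted with TRIZOL and Qiagen columns, and cDNA was end-labelled with biotin. Each of the 6 combinations of genotype and time had 2 arrays. The title of 1 array in each pair carries the mark Rep; these arrays are called the set marked Rep, and the others the unmarked set. The labels do not say whether the arrays come from separate mice or separate cultures, so the p-values measure the spread between these samples.

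The deposited table holds 1 log2 value per probe set and array for 28853 probe sets, from 3.49 to 15.38. How the authors summarised and normalised the arrays is not given in the sources used here. The medians of the 12 arrays ran from 7.39 to 7.50, a range of 0.11 that exceeded the limit of 0.1 set before the data were examined, so the values were quantile normalised between arrays. Exactly equal values made up 0.0069% to 0.0173% of the probe sets in pairs of replicate arrays. Values of replicate arrays correlated with r from 0.991 to 0.997 across probe sets, and their root mean square difference was 0.21 to 0.26 on the log2 scale in the transgenic groups and 0.31 to 0.34 in the WT groups.

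Gene symbols came from the array annotation and were looked up by Entrez number in a RefSeq gene table, in which 91 of them were not found. Of all probe sets, 21789 had 1 symbol, 1621 had several and 5443 had none; the 23410 with at least 1 symbol were tested. Genes without a probe set of their own were not analysed here, and some items are not reported here. Tests used limma 3.58.1 in R 4.3.3: 1 fit of all 12 arrays with a mean for each of the 6 groups, moderated variances (6 residual and 3.05 prior degrees of freedom) and Benjamini-Hochberg adjusted p under 0.05 within each of 10 comparisons. The comparisons were transgenic against WT at each time and averaged over the 3 times, each stimulated time against 0 h within each genotype, and the difference between genotypes in the response at 6 h and at 24 h. Differences are on the log2 scale with the standard error of the fit. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

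The comparisons, the rule for genes to be named and 43 gene lists with 669 entries, of which 608 were measured, were fixed before the data were examined. The 42 lists with at least 3 measured members were tested with limma's camera at a preset correlation between genes of 0.01, with 1 probe set per gene and adjustment over 420 tests of lists and comparisons. Camera compares a list with all other genes, and a list's median log2 difference is given as its size. The rule named, in each comparison, the 10 largest differences in each direction past the threshold without overlap between the groups, leaving out predicted genes; where fewer than 5 passed, the 5 of the largest moderated statistic, given as values only; up to 4 members of each list with the smallest p; and Ppp2ca and a fixed set of PP2A, cytokine and T cell genes. Other genes named were chosen after their values were seen, which is said where they appear.

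Whether the mark Rep pairs samples across groups was checked with the deviations of the first array of each pair from its group mean. All 15 correlations between groups were positive, from 0.138 to 0.591, so samples with the same mark shared variation, and a fit with the mark as a block was run for every result. Differences within the unmarked set and within the set marked Rep are given beside pooled ones. The other alternatives were the values as deposited, median centring, leaving out the 40% dimmest probe sets, testing all rows of the table, 1 probe set per gene, trended and robust moderation, array weights, a fit of the compared groups only, a minimum of 2-fold, camera with an estimated correlation, the rotation test fry, lists without shared genes, and leaving out each array in turn. Leaving out the 3 WT arrays marked Rep, and a fit with the mean neutrophil marker level of each array as a covariate, were chosen after marker levels had been seen. The procedure was tested on simulated data with 200 changed probe sets among 23410: for 1 time point it recovered 38% of changes of 0.5, 84% of changes of 1 and 98% of changes of 2 on the log2 scale, with 12 false calls among 171. The simulated noise was independent between arrays, without the variation shared by the mark Rep. Fewer true changes would also make the adjusted threshold stricter. The shares therefore do not measure the power in the real data.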

Results

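The data describe naive CD4 T cells from WT mice and from mice transgenic for PP2Ac, before stimulation and after 6 h or 24 h of stimulation through CD3 and CD28, with 2 arrays for each genotype and time. The number of arrays limits the precision of every comparison. Differences are log2 values ± SE.

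Before stimulation, the largest difference between the genotypes was in Nova1, which encodes a splicing regulator known mainly from neurons. Its probe set 10400155 read higher in transgenic cells by at least 5.81, and 10400157 by 5.53 (limma adjusted p = 1.5e-06 and 3.0e-05, n = 2 arrays per group). The former read 5.47 in WT, below the lower quartile of every array (5.75 to 5.86), and 11.28 in transgenic cells, and the latter 6.10 and 11.63. Since the WT reading of 10400155 lies near the low end of the arrays, its differences here and below are called lower bounds. This concerns the low WT reading alone and not the spread between arrays, as the value at 0 h has an SE of 0.17 and was 5.56 in the set marked Rep. The WT reading of 10400157 lies above those quartiles here, so whether its differences are lower bounds cannot be told. Nova1 differences are not ranked between times. Ppp2ca (10375926), the gene of the transgene product, read 13.15 in WT and 13.89 in transgenic cells, a difference of 0.74 ± 0.08 (adjusted p = 0.055, and 0.035 with the replicate block). Ppp2ca also passed with the values as deposited (adjusted p = 0.043), without the dimmest probe sets (0.042), with array weights (0.029) and with trended and robust moderation (0.0019). Ppp2cb, the gene of the other catalytic subunit, and Ppp2r1a, the gene of a scaffold subunit, differed by -0.04 ± 0.09 and -0.02 ± 0.08 and did not pass. Both Nova1 probe sets were the only ones of 23410 past the threshold (2 higher, 0 lower, 834 had an unadjusted p under 0.05). With no difference at all, a share of 0.05 of the 23410 would have such a p, which is more than was found at any single time. The block gave 4, adding Ppp2ca and Tspan33, a tetraspanin gene (0.71 ± 0.13, adjusted p = 1, and 0.045 with the block).

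Among genes named as values only at 0 h were Cldn13, a claudin gene (0.85 ± 0.11), Kel, which encodes the Kell antigen of red cells (1.10 ± 0.20), and Capn11, a calpain gene (-0.76 ± 0.15). Of the 25 measured PP2A subunits and regulators, 0 passed and 1, Ppp2ca, passed when adjusted over the list alone; the list's median was -0.03 and its mean 0.01 (camera adjusted p = 0.92). Genes of the early T cell receptor response stood higher as a group, with a median of 0.23 and 19 of 22 members positive (0.17 in the unmarked set and 0.29 in the set marked Rep, adjusted p = 5.3e-06). With an estimated correlation the adjusted p was 0.47. No member passed, over all genes or adjusted over the list alone; Fos and Egr1, immediate early transcription factors, read 0.50 ± 0.21 and 0.34 ± 0.17. The shift fell to 0.09 (adjusted p = 0.14) without the second WT array at 0 h. Interferon-stimulated genes had a median of 0.42, with 23 of 24 positive (0.50 and 0.27 in the sets, adjusted p = 2.9e-05, and adjusted p = 0.67 with an estimated correlation), which became 0.16 (adjusted p = 0.13) without the first transgenic array at 0 h.

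Markers of other blood cells also differed at 0 h. Dendritic cell markers had a median of 0.35 (0.23 and 0.51 in the sets, adjusted p = 2.4e-05, and adjusted p = 0.38 with an estimated correlation), with 1 of 7 past adjusted over the list alone and Itgax, an integrin of dendritic cells, at 0.55 ± 0.13. Monocyte and neutrophil markers had medians of 0.68 and 1.22 (adjusted p = 0.00037 and 0.018, adjusted p = 0.69 and 0.77 with an estimated correlation), but 0.13 and -0.00 in the unmarked set against 1.31 and 2.39 in the set marked Rep. Without the 3 WT arrays marked Rep these medians were 0.03 and -0.48, and the neutrophil call ended at 0.76 (adjusted p = 0.28) without the first transgenic array. NK cell and B cell markers had medians of 0.28 and 0.21 (adjusted p = 0.0041 and 0.0026, adjusted p = 0.53 and 0.67 with an estimated correlation), calls that ended at 0.07 and 0.12 without the first WT array at 0 h. The NK cell call also ended at 0.16 without the second transgenic array. The 2 measured erythroid markers, Slc4a1, the red cell anion exchanger, and Alas2, an enzyme of haem synthesis, read 1.65 ± 0.39 and 0.84 ± 0.23, both past only when adjusted over the list alone. Antigen-experienced T cell genes had a median of 0.22 (adjusted p = 0.00077, and adjusted p = 0.52 with an estimated correlation), which ended at -0.03 without the WT arrays marked Rep.

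At 6 h of stimulation, Nova1 was higher in transgenic cells, by at least 3.94 in 10400155 and by 4.37 in 10400157 (adjusted p = 4.8e-05 and 0.00024). Th17 genes, those of the IL-17 producing helper lineage, stood higher as a group. The Th17 median was 0.37, with 9 of 11 members positive (0.22 in the unmarked set and 0.35 in the set marked Rep, adjusted p = 2.7e-08). The adjusted p was 0.26 with an estimated correlation. Il17f and Il17a, the genes of the cytokines IL-17F and IL-17A, read 1.63 ± 0.22 and 0.89 ± 0.13 (adjusted p = 0.26 for both). With the block Il17f passed (adjusted p = 0.0049) and Il17a did not (adjusted p = 0.17). The neutrophil marker covariate gave adjusted p = 0.024 for Il17f and 0.37 for Il17a. Over all genes 0 of the 11 passed, and 2 did when adjusted over the list alone. Ppp2ca read 13.36 in WT and 13.75 in transgenic cells (0.38 ± 0.08, adjusted p = 1).

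T helper cytokine and chemokine genes had a median of 0.25 at 6 h, with 21 of 25 positive and 2 past adjusted over the list alone (0.13 and 0.34 in the sets, adjusted p = 6.4e-08). An estimated correlation gave adjusted p = 0.38. The call ended at 0.12 (adjusted p = 0.056) without genes of more than 1 list. Ifng, the gene of interferon gamma, read 0.75 ± 0.42 and Ccl20, a ligand of the Th17 receptor CCR6, 0.37 ± 0.16. Th1 genes had a median of 0.27 with 11 of 12 positive (0.27 and 0.21 in the sets, adjusted p = 7.3e-05, and adjusted p = 0.32 with an estimated correlation), a call that ended at 0.14 (adjusted p = 0.065) without the first WT array at 6 h. IL-2 and STAT5 targets had a median of 0.17 (0.22 and 0.14 in the sets, adjusted p = 0.0021). Under an estimated correlation the adjusted p was 0.49. The interferon-stimulated genes had a median of 0.55 with 24 of 24 positive (adjusted p = 2.7e-10, and adjusted p = 0.47 with an estimated correlation), but -0.13 in the unmarked set and 1.28 in the set marked Rep, and -0.23 (adjusted p = 0.090) without the WT arrays marked Rep. Monocyte markers followed the same arrays, with a median of 0.60 that was -0.12 in the unmarked set and 1.43 in the set marked Rep (adjusted p = 0.0016). The list had adjusted p = 0.71 with an estimated correlation. Neutrophil markers had a median of 0.98 (-0.20 and 2.05 in the sets, adjusted p = 0.063, and 0.0030 with the block). NK cell and dendritic cell markers had medians of 0.40 and 0.15 (0.77 and 0.20, and 0.21 and 0.08, in the sets, adjusted p = 0.00045 and 0.043, adjusted p = 0.47 and 0.52 with an estimated correlation). Both calls ended without the first WT array at 6 h (0.16 and -0.04) or the second transgenic array (0.39 and -0.11).

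Only the Nova1 probe sets passed at 6 h (2 higher, 0 lower, 610 with an unadjusted p under 0.05). The block gave 3 higher and 1 lower, adding Il17f and Mid1, the gene of a ubiquitin ligase that acts on the catalytic subunit of PP2A (10603208, -0.95 ± 0.11, adjusted p = 0.10, and 0.033 with the block). Values not past the threshold included Nnt, the gene of the mitochondrial transhydrogenase (0.48 ± 0.07), and Wdfy1, the gene of an endosomal adaptor (0.57 ± 0.09). The genes of IL-2, CD69, the IL-2 receptor alpha chain and IRF4, all induced by T cell receptor signals, differed by 0.10 ± 0.55, -0.00 ± 0.31, 0.05 ± 0.33 and -0.02 ± 0.18.

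At 24 h, the Th17 and interferon-stimulated groups stood higher in transgenic cells in both sets of arrays. The Th17 median was 0.72, with 9 of 11 positive and 5 past adjusted over the list alone (0.38 in the unmarked set and 0.48 in the set marked Rep, adjusted p = 2.1e-08). With an estimated correlation the adjusted p was 0.26. Il23r, the receptor gene for the cytokine that maintains Th17 cells, read 1.14 ± 0.16 (adjusted p = 0.31, and 0.032 with the block), Il17f 1.40 ± 0.22 (0.44, and 0.017 with the block) and Il17a 0.85 ± 0.13 (0.31). Ccl20 read 0.72 ± 0.16 and Ccr6 0.73 ± 0.23. The median of the interferon-stimulated genes was 0.87, with 24 of 24 positive and 2 past adjusted over the list alone (0.78 and 0.91 in the sets, adjusted p = 9.9e-15). The adjusted p was 0.43 with an estimated correlation. Xaf1, an interferon-induced apoptosis factor, read 1.01 ± 0.20, Stat2, a mediator of interferon signals, 0.75 ± 0.15, and Irf7, a regulator of interferon genes, 1.17 ± 0.34.

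Monocyte markers stood beside these groups at 24 h with a median of 0.72 (-0.23 in the unmarked set and 1.66 in the set marked Rep, adjusted p = 0.00028). An estimated correlation gave adjusted p = 0.69. Without the WT arrays marked Rep they turned to -0.22. B cell and NK cell markers had medians of 0.28 and 0.36 (adjusted p = 5.6e-05 and 0.0026, adjusted p = 0.52 for both with an estimated correlation), of which the former ended at 0.08 without the WT arrays marked Rep and the latter at 0.08 without the first transgenic array at 24 h. Dendritic cell markers had a median of 0.09 (0.03 and 0.27 in the sets, adjusted p = 0.0093, and adjusted p = 0.47 with an estimated correlation), a call that ended without the second WT array at 24 h (0.13, adjusted p = 0.12) or the second transgenic array (0.09, adjusted p = 0.075), though neither median was smaller. Neutrophil markers did not pass (median 0.90, -0.75 and 2.37 in the sets, adjusted p = 0.26). Th1 genes were 12 of 12 positive with a median of 0.26 (0.19 and 0.37 in the sets, adjusted p = 4.3e-05, and adjusted p = 0.32 with an estimated correlation), among them Ccl5 (0.54 ± 0.15) and Ifng (0.91 ± 0.42). Ifng ran from 0.25 to 1.56 when 1 array was left out. Cytokine and chemokine genes had a median of 0.22 and 4 members past adjusted over the list alone (adjusted p = 9.8e-05, and adjusted p = 0.47 with an estimated correlation); the call ended at 0.07 without the first WT array at 24 h, at 0.16 without the second transgenic array, and at 0.05 without genes of more than 1 list. Chemokine and sphingosine phosphate receptors had a median of 0.40, with Cxcr6 at 0.65 ± 0.12 (adjusted p = 0.00076, and adjusted p = 0.38 with an estimated correlation), and -0.01 without the WT arrays marked Rep.

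In the other direction at 24 h, ribosome biogenesis genes had a median of -0.21 with 0 of 26 positive (-0.06 and -0.33 in the sets, adjusted p = 1.4e-09, and adjusted p = 0.47 with an estimated correlation), and cholesterol synthesis genes -0.16 with 0 of 16 positive (-0.08 and -0.16, adjusted p = 0.00049). Under an estimated correlation the adjusted p of the latter was 0.48. Cad, which encodes the first enzyme of pyrimidine synthesis, read -0.23 ± 0.10 and Sqle, an enzyme of sterol synthesis, -0.31 ± 0.13. Both calls ended without the WT arrays marked Rep, at -0.07 and -0.03, and the latter also without the first transgenic array at 24 h, at -0.10. The medians of -0.07 and -0.03 rest on leaving out the second WT array at 24 h, the only array of that set in this comparison. G1/S genes had a median of -0.15 with 1 of 29 positive (0.03 and -0.33 in the sets, adjusted p = 0.0026, and adjusted p = 0.83 with an estimated correlation), which turned to 0.16 (adjusted p = 0.00050) without the second transgenic array at 24 h and ended at -0.0033 without the first WT array. Of single genes, Nova1 passed (at least 4.31 in 10400155 and 4.84 in 10400157, adjusted p = 2.2e-05 and 9.6e-05) and no other (2 higher, 0 lower, 997 with an unadjusted p under 0.05). The count was 4 with the block, adding Il17f and Il23r, 5 without the WT arrays marked Rep and 6 without the second transgenic array at 24 h. Ppp2ca read 13.21 in WT and 13.81 in transgenic cells (0.60 ± 0.08, adjusted p = 0.28, and 0.013 with trended and robust moderation). Il2 read -0.65 ± 0.55, and Akr1c12, an aldo-keto reductase gene, -1.05 ± 0.22.

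**Figure D1:**
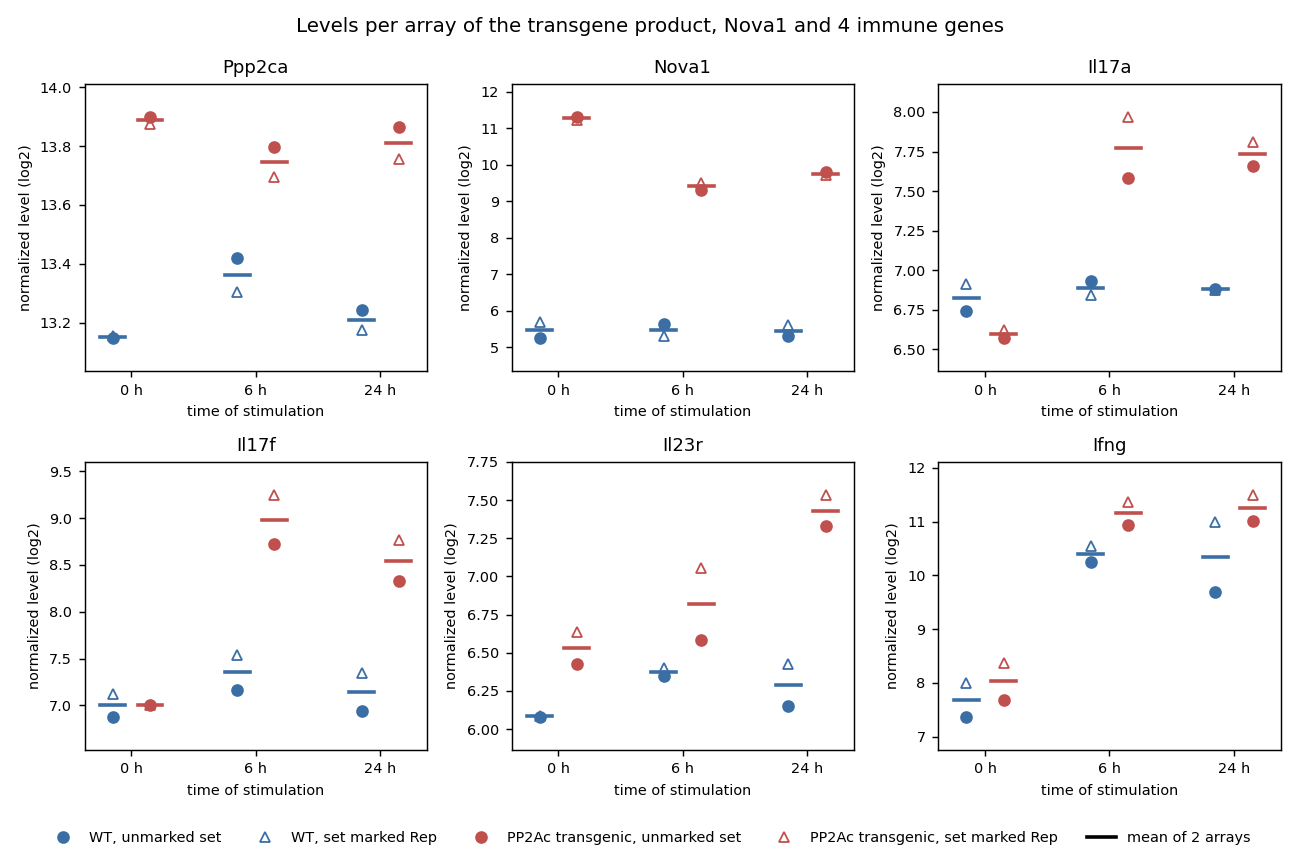
Log2 level of 6 genes in each array (vertical axis) by genotype and hours of stimulation (horizontal axis); filled circles are the unmarked set, open triangles the set marked Rep, and bars the mean of both arrays. Nova1 and Ppp2ca separate the genotypes at every time, and the Il17f means differ by 1.63 at 6 h and 1.40 at 24 h.

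Averaged over the 3 times, 5 probe sets were higher and 1 was lower in transgenic cells (1484 had an unadjusted p under 0.05). Nova1 led with at least 4.69 in 10400155 and 4.91 in 10400157 (adjusted p = 7.4e-08 and 6.2e-07, 6 arrays per genotype). Deviations of WT arrays with the same mark correlated between times at 0.59, 0.56 and 0.47, and those of transgenic arrays at 0.14 to 0.30. Should arrays of a genotype with the same mark share a mouse or culture, they are not 6 independent samples. The p-values of all averages would then be too small. The block takes out only what both genotypes share by mark. Ppp2ca passed at 0.57 ± 0.05 (adjusted p = 0.0044), and was 0.55 and not past without the WT arrays marked Rep. Mid1 was lower, at -0.74 ± 0.06 (adjusted p = 0.0060), and Nnt, whose gene carries a deletion in the C57BL/6J substrain, and Wdfy1 were higher, at 0.43 ± 0.04 and 0.48 ± 0.05 (adjusted p = 0.0082 and 0.034). Without the WT arrays marked Rep these values were -0.69, 0.44 and 0.54 and none passed (adjusted p = 0.082, 0.16 and 0.14). Wdfy1 did not pass when any 1 of the 12 arrays was left out, and Nnt did not without either transgenic array at 0 h, the first at 24 h, or the second WT array at 6 h or 24 h (adjusted p up to 0.066). Their differences without 1 array were 0.45 to 0.51 and 0.42 to 0.44. Median centring also ended both calls (Wdfy1 0.48, adjusted p = 0.10, and Nnt 0.39, adjusted p = 0.11), and trended and robust moderation that of Wdfy1 (adjusted p = 0.060). The block raised the count to 17 higher and 1 lower, adding Il17f (1.01 ± 0.13, adjusted p = 0.087, and 0.0024 with the block), Il23r (0.68 ± 0.09, 0.10 and 0.010) and Itgax (0.54 ± 0.08, 0.12 and 0.010). Il17f also passed with the values as deposited, median centring, and trended and robust moderation (adjusted p = 0.045, 0.045 and 0.043). With the neutrophil marker covariate Il17f, Il23r and Itgax passed (adjusted p = 0.0098, 0.039 and 0.016). The 9 others added by the block are named after their values were seen. Of these, 3 were probe sets of Igha, an antibody heavy chain of B lineage cells (1 of them shared with Ighv3-6). The rest were Cd86 and Fscn1, expressed by dendritic cells, Klrb1b, an NK cell receptor gene, Lrrk1, Car13 and Tspan33. The 9 read 0.38 to 1.34 (adjusted p from 0.088 to 0.77, and from 0.010 to 0.050 with the block). The count ranged from 4, without the first transgenic array at 0 h, to 19, without the first WT array at 6 h.

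The Th17 genes averaged over the times had a median of 0.32 with 10 of 11 positive and 5 past adjusted over the list alone (0.16 in the unmarked set and 0.30 in the set marked Rep, adjusted p = 1.0e-09). The list had adjusted p = 0.26 with an estimated correlation. At 0 h Il17f read 0.0052 and Il17a -0.23, so the averages of these cytokine genes stem from 6 h and 24 h. Il23r read 0.45 at 0 h and did not pass there. Interferon-stimulated genes had a median of 0.68 with 24 of 24 positive and 6 past adjusted over the list alone (0.45 and 0.85 in the sets, adjusted p = 4.9e-18, and adjusted p = 0.38 with an estimated correlation), such as Xaf1 (0.63 ± 0.12), Stat2 (0.40 ± 0.09) and Zbp1, a sensor of viral nucleic acid (0.33 ± 0.09). Beside them stood monocyte markers at 0.71 (-0.17 and 1.48 in the sets, adjusted p = 5.2e-07, and adjusted p = 0.52 with an estimated correlation) and neutrophil markers at 1.03 (-0.29 and 2.32, adjusted p = 0.0061, and adjusted p = 0.71 with an estimated correlation), which turned to -0.14 and -0.68 without the WT arrays marked Rep. The neutrophil call ended without the second WT array at 0, 6 or 24 h alone, at 0.43, 0.53 and 0.41. Th1 genes were 12 of 12 positive with a median of 0.26 (0.24 and 0.23 in the sets, adjusted p = 2.3e-07, and adjusted p = 0.26 with an estimated correlation), and cytokine genes 21 of 25 with a median of 0.18 (0.16 and 0.15, adjusted p = 3.0e-07). For the cytokine genes adjusted p = 0.38 with an estimated correlation. NK cell, B cell and dendritic cell markers had medians of 0.36, 0.23 and 0.16, positive in both sets (adjusted p = 1.0e-05, 1.1e-05 and 7.3e-05, adjusted p = 0.39, 0.48 and 0.38 with an estimated correlation). The genes of the DNA methylation machinery did not shift (median -0.01, adjusted p = 0.75), nor did the 5 methylation-sensitive T cell genes (0.06, adjusted p = 0.18). Itgal, which encodes CD11a, read 0.06 ± 0.06, Cd70 0.17 ± 0.14 and Dnmt1, the maintenance methyltransferase gene, 0.01 ± 0.07.

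**Figure D2:**
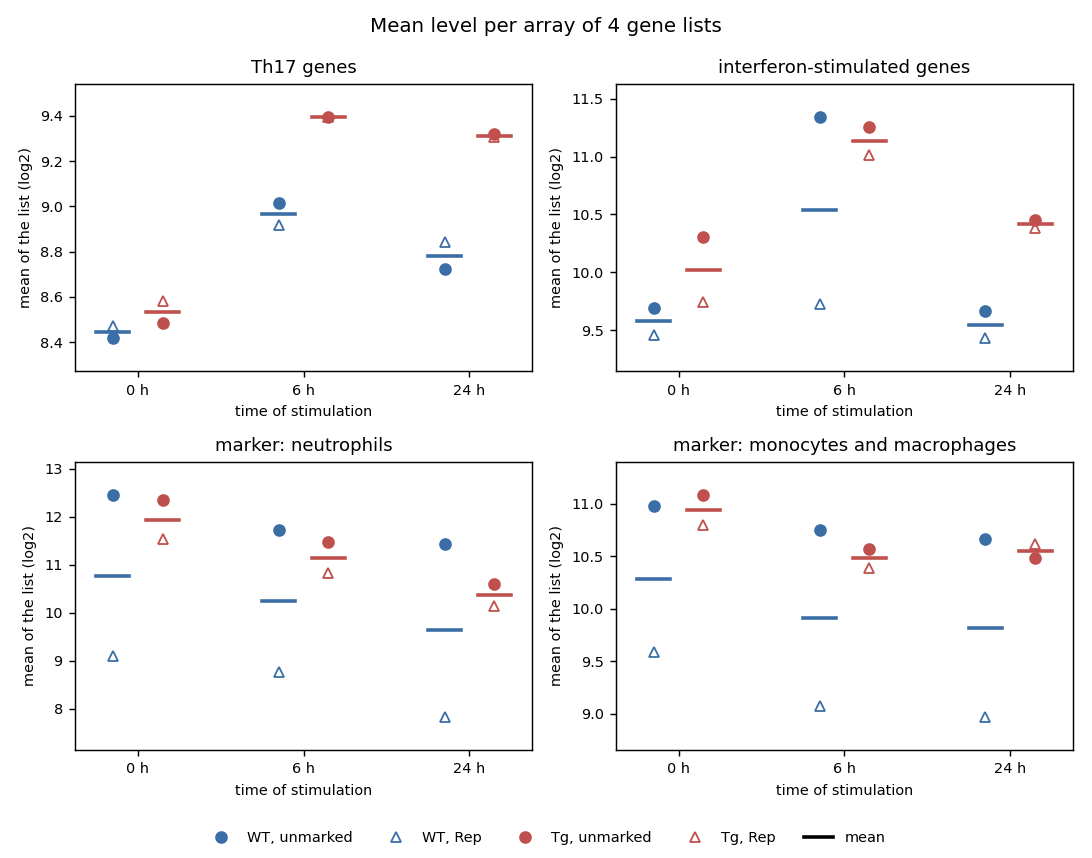
Mean log2 level of 4 gene lists in each array (vertical axis) by genotype and hours of stimulation (horizontal axis), with filled circles for the unmarked set, open triangles for the set marked Rep and bars for the mean of both. Neutrophil and monocyte markers are lowest in the WT arrays marked Rep, at 9.10, 8.76 and 7.84 for neutrophil markers at 0, 6 and 24 h, whereas both Th17 levels of the transgenic cells exceed both WT levels at 6 and 24 h.

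Stimulation for 6 h changed WT cells broadly. In them 2955 probe sets rose and 3254 fell, 1644 of them by at least 2-fold. Il2, the growth factor gene of activated T cells, rose by 4.49 ± 0.55 and Lag3, an inhibitory receptor gene, by 3.58 ± 0.18. Spry1, a feedback inhibitor of ERK signals, rose by 3.55 ± 0.17, and Ifng, Irf4 and Il2ra rose by 2.71 ± 0.42, 2.99 ± 0.18 and 3.06 ± 0.33 (adjusted p from 8.6e-06 to 0.0012 for these 6 genes). Other large rises were those of Bcat1, a branched-chain amino acid transaminase (4.11 ± 0.55), Ccl22, a ligand of CCR4 (3.80 ± 0.48), Dctd, a deoxycytidylate deaminase (3.85 ± 0.11), and Cxcl10, an interferon-induced chemokine (3.46 ± 0.66). Among the largest falls were those of Rflnb, an actin regulator (-3.80 ± 0.32), Tdrp (-3.39 ± 0.25), Pde2a, a phosphodiesterase (-3.04), and Il7r, the IL-7 receptor gene of resting T cells (-2.93 ± 0.35). Ppp2ca was not past the threshold (0.21 ± 0.08, adjusted p = 0.090).

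By group, 25 of 26 ribosome biogenesis genes rose and 0 fell at 6 h in WT (median 1.84, adjusted p = 1.0e-22, Srm, a polyamine synthase, 2.59 ± 0.13, Cad 2.31 ± 0.10). Cholesterol synthesis genes rose in 13 of 16 cases (median 0.92, adjusted p = 3.3e-09, Idi1 2.55 ± 0.13), heat shock genes in 8 of 11 (0.53, 5.4e-06, Hspd1 2.17 ± 0.11) and IL-2 and STAT5 targets in 10 of 13 (1.15, 9.1e-06, Cish 2.36 ± 0.21). These 4 lists had adjusted p = 0.38 with an estimated correlation. Among 25 cytokine and chemokine genes 13 rose and 1 fell, 16 and 1 when adjusted over the list alone (median 1.26, adjusted p = 1.4e-06, and adjusted p = 0.38 with an estimated correlation, Tnf 2.29 ± 0.22, Lif 2.61 ± 0.27). Of 22 early receptor response genes 14 rose and 2 fell (1.08, adjusted p = 5.7e-07, and adjusted p = 0.43 with an estimated correlation, Myc 2.23 ± 0.20, Tnfrsf9 2.56 ± 0.19). Genes of the naive and quiescent state moved the other way, with 0 up and 15 of 22 down (-1.01, adjusted p = 1.7e-06, and adjusted p = 0.49 with an estimated correlation, Tob1, an antiproliferative factor, -1.59 ± 0.12, Lef1 -0.94 ± 0.09), as did FOXO targets, 8 of 12 down (-1.09, adjusted p = 0.00081, and adjusted p = 0.63 with an estimated correlation, S1pr1 -1.32 ± 0.20).

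Metabolic and stress genes rose in part at 6 h in WT: 9 of 15 glycolysis genes (median 0.58, adjusted p = 0.0010, and adjusted p = 0.47 with an estimated correlation, Hk2 2.34 ± 0.31), 15 of 27 oxidative phosphorylation genes (0.31, adjusted p = 5.5e-05, and adjusted p = 0.60 with an estimated correlation, Cox5a 0.75 ± 0.10) and 11 of 22 amino acid transport and ATF4 target genes (1.40, adjusted p = 1.5e-05, and adjusted p = 0.69 with an estimated correlation, Shmt2 2.11 ± 0.27). Unfolded protein response genes split into 11 up and 2 down of 19 (0.51, adjusted p = 0.00062, and adjusted p = 0.38 with an estimated correlation, Hspa5 1.02 ± 0.08). Of 24 interferon-stimulated genes 2 rose, Bst2 (1.26 ± 0.27) and Usp18 (1.48 ± 0.39); the list's median of 1.03 (adjusted p = 0.0017, and adjusted p = 0.77 with an estimated correlation) was 1.76 in the unmarked set and 0.41 in the set marked Rep, and 0.25 (adjusted p = 0.42) without the first WT array at 6 h. Replication genes of the G1/S step did not shift (2 up, 2 down of 29, median 0.22, adjusted p = 0.30), nor did Th17 genes (4 up, 1 down of 11, 0.35, adjusted p = 0.068), with Il17a at 0.06 ± 0.13 and Il17f at 0.35 ± 0.22.

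In WT cells at 24 h, 3015 probe sets rose and 3230 fell, 1355 of them by at least 2-fold. Replication genes led: 27 of 29 G1/S genes rose (28 adjusted over the list alone, median 2.24, adjusted p = 8.2e-23, and adjusted p = 0.38 with an estimated correlation), among them E2f1 (2.72 ± 0.16) and Mcm3, a subunit of the replicative helicase (2.24 ± 0.13). Chek1, a replication checkpoint kinase, rose by 4.41 ± 0.18, Dtl by 4.09 ± 0.27 and Orc1, part of the origin recognition complex, by 3.86 ± 0.23. Of 24 G2/M genes 12 rose, 17 adjusted over the list alone (median 2.04, 2.46 in the unmarked set and 1.55 in the set marked Rep, adjusted p = 9.1e-07, and adjusted p = 0.69 with an estimated correlation), with Top2a at 2.79 ± 0.51 (10390707; its dim probe set 10390746 read 0.23) and Cdk1, the mitotic kinase, at 2.84 ± 0.54. Lag3 rose by 4.52 ± 0.18, Il2 by 3.99 ± 0.55, Lif by 3.84 ± 0.27, Socs2, a STAT5-induced feedback gene, by 3.65 ± 0.29 (10394674; 2.10 in 10372069) and Il12rb1, a receptor chain for IL-12 and IL-23, by 3.40 ± 0.22. Falls were led by Rgs2, a regulator of G protein signals (-3.29 ± 0.30), Trf, the transferrin gene (-2.82), and Cd209a, a dendritic cell lectin (-2.68).

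The biosynthetic groups were also up at 24 h in WT: 23 of 26 ribosome biogenesis genes (median 1.27, adjusted p = 2.3e-17, Nme1 2.25 ± 0.13), 15 of 16 cholesterol synthesis genes (0.82, 1.0e-10), 12 of 15 glycolysis genes (0.76, 2.4e-06, Tpi1 2.30 ± 0.28) and 11 of 13 IL-2 and STAT5 targets (1.43, 3.2e-09), each with adjusted p = 0.38 with an estimated correlation. Oxidative phosphorylation genes rose in 21 of 27 cases (0.48, adjusted p = 1.4e-09). The adjusted p was 0.44 with an estimated correlation. Th2 genes rose in 5 of 11 cases (0.28, adjusted p = 0.010, and adjusted p = 0.43 with an estimated correlation), led by the chemokine receptors Ccr4 (3.47 ± 0.22) and Ccr8 (3.22 ± 0.40), which other activated T cells also carry. Leaving out genes of more than 1 list ended the Th2 call at 0.01 (adjusted p = 0.83). Cytokine genes had 12 up and 1 down of 25 (0.85, adjusted p = 4.5e-06). An estimated correlation gave adjusted p = 0.42. Naive and quiescence genes fell in 16 of 22 cases (-0.59, adjusted p = 5.8e-08, and adjusted p = 0.47 with an estimated correlation, Klf3 -1.39 ± 0.17), and FOXO targets in 8 of 12, 12 of them adjusted over the list alone (-1.18, adjusted p = 2.6e-06). For FOXO targets adjusted p = 0.47 with an estimated correlation. Dendritic cell markers fell in 4 of 7 cases (-0.71, adjusted p = 0.0092). The list had adjusted p = 0.47 with an estimated correlation. Without the WT arrays marked Rep the count of changed probe sets was 2870.

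Transgenic cells at 6 h had 2923 probe sets up and 3012 down, 1597 of them by at least 2-fold. Il2 rose by 4.70 ± 0.55, Lag3 by 3.75 ± 0.18, Ifng by 3.13 ± 0.42, Irf4 by 2.58 ± 0.18 and Il1a, an inflammatory cytokine gene, by 3.81 ± 0.61. Rflnb (-4.08) and Il7r (-3.19 ± 0.35) fell. Il17a rose by 1.18 ± 0.13 (adjusted p = 0.00017) and Il17f by 1.98 ± 0.22 (adjusted p = 0.00023), and 7 of 11 Th17 genes rose and 1 fell, 8 and 1 adjusted over the list alone (median 0.52, adjusted p = 0.0016). With an estimated correlation the adjusted p was 0.38. The difference from the WT responses of Il17a and Il17f did not pass (adjusted p = 1 for both). The Th17 call ended at 0.41 (adjusted p = 0.21) without genes of more than 1 list. Cytokine and chemokine genes rose in 18 of 25 cases and 20 adjusted over the list alone (1.54, adjusted p = 1.5e-09). The adjusted p was 0.38 with an estimated correlation. Interferon-stimulated genes rose in 7 of 24 cases and 10 adjusted over the list alone (0.96, 0.85 in the unmarked set and 1.27 in the set marked Rep, adjusted p = 0.00021, and adjusted p = 0.70 with an estimated correlation, Usp18 1.70 ± 0.39). Ribosome biogenesis genes rose in 25 of 26 cases (1.86, adjusted p = 1.2e-22, and adjusted p = 0.38 with an estimated correlation, Srm 2.72 ± 0.13), and naive and quiescence genes fell in 14 of 22 (-1.03, adjusted p = 5.0e-07). An estimated correlation gave adjusted p = 0.47 for the latter.

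In transgenic cells at 24 h, 2801 probe sets rose and 2768 fell, 1153 of them by at least 2-fold. The G1/S genes rose in 27 of 29 cases, all 29 adjusted over the list alone (median 2.10, adjusted p = 8.2e-23, and adjusted p = 0.38 with an estimated correlation, E2f1 2.41 ± 0.16, Mcm3 2.00 ± 0.13). G2/M genes rose in 8 of 24 cases, 12 adjusted over the list alone (1.76, adjusted p = 1.1e-05, and adjusted p = 0.71 with an estimated correlation), with medians of 2.71 in the unmarked set and 0.65 in the set marked Rep. Lag3 rose by 4.77 ± 0.18, Il2 by 3.46 ± 0.55 and Ifng by 3.22 ± 0.42. Th17 genes rose in 8 of 11 cases and fell in 1, 9 and 1 adjusted over the list alone (0.86, adjusted p = 0.00032, and adjusted p = 0.38 with an estimated correlation), with Il17a at 1.14 ± 0.13 and Il17f at 1.54 ± 0.22. Without genes of more than 1 list the Th17 median was 0.47 and not past (adjusted p = 0.17), and the difference from the WT responses of both genes did not pass at 24 h (adjusted p = 1). Ribosome biogenesis genes had 23 of 26 up and 1 down (1.09, adjusted p = 3.2e-15, and adjusted p = 0.38 with an estimated correlation), and cholesterol synthesis genes 11 of 16 up (0.64, adjusted p = 8.9e-09). For the latter adjusted p = 0.38 with an estimated correlation. The erythroid markers Slc4a1 (-2.93 ± 0.39) and Alas2 (-1.22) fell. The count of changed probe sets, 5569, dropped to 3563, 3077 and 3244 without the first array at 0 h, the first at 24 h and the second at 0 h.

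**Figure D3:**
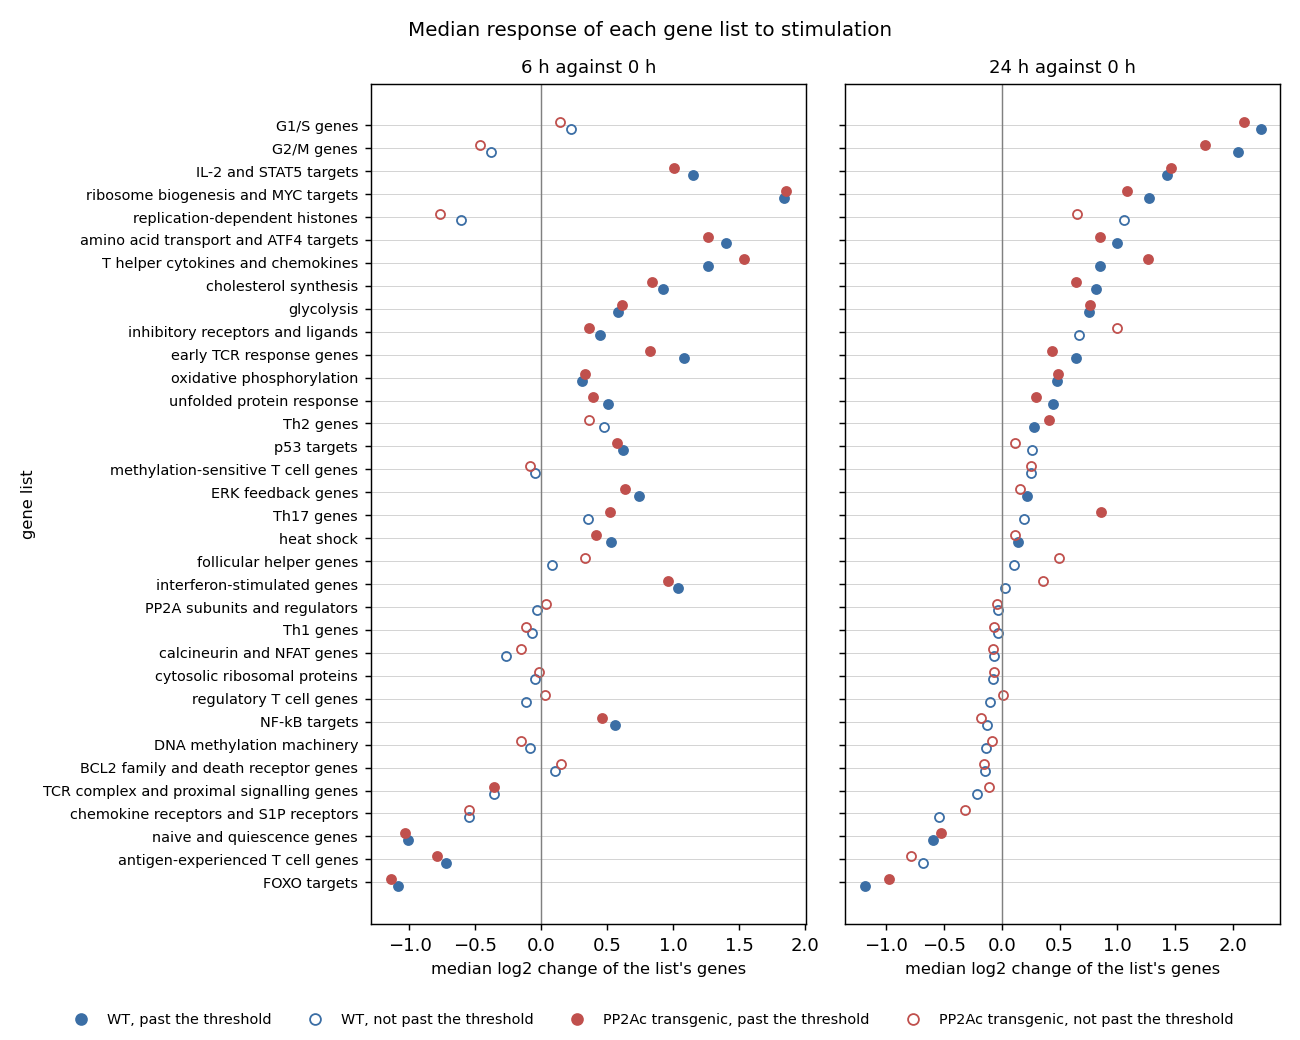
Median log2 response to stimulation (horizontal axis) of each gene list that is not a cell type marker (vertical axis) at 6 h and 24 h, WT in blue and transgenic in red; filled symbols are past the threshold of camera, open symbols are not. Ribosome biogenesis genes lie at 1.84 and 1.86 at 6 h, and G1/S genes at 2.24 and 2.10 at 24 h, in WT and transgenic cells.

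The responses of the genotypes, which share no arrays, overlapped beyond independent calls. At 6 h, 2558 probe sets rose in both (369 expected of independent calls) and 2694 fell in both (419 expected), against 1 called in opposite directions, and the log2 responses correlated with r = 0.958 and rho = 0.848 across probe sets, which are not independent replicates. At 24 h the numbers were 2421 and 2413 (361 and 382 expected), 2 in opposite directions, r = 0.934 and rho = 0.820. Among the probe sets called in either genotype, the slope of the transgenic on the WT response was 0.969 at 6 h and 0.903 at 24 h. Spread between the WT arrays also lowers this slope, which was not tested.

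Tested directly, the difference between the 2 responses passed for 0 probe sets at 6 h and 0 at 24 h (limma, 420 and 625 with an unadjusted p under 0.05). The cytokine genes of the Th17 lineage had large values among them: Il17a responded more in transgenic cells by 1.11 ± 0.18 at 6 h and 1.08 ± 0.18 at 24 h, and Il17f by 1.63 ± 0.32 and 1.40 ± 0.32 (adjusted p = 1 for each). Nova1 (10400155) read -1.87 ± 0.24 at 6 h (adjusted p = 0.58), with levels of 11.28 at 0 h, 9.41 at 6 h and 9.76 at 24 h in transgenic cells and of 5.47, 5.47 and 5.45 in WT, where a fall could not be measured so near the low end of the arrays. The size depended on the probe set: 10400157 read -1.16 at 6 h and -0.68 at 24 h, where 10400155 read -1.50 at 24 h. Of the lists, Th17 genes had a median of 0.11 at 6 h and 0.44 at 24 h (adjusted p = 0.0063 and 0.00041, adjusted p = 0.38 for both with an estimated correlation), both calls ending when genes of more than 1 list were left out (0.06 at both times). The 6 h call also ended without the first transgenic array at 0 h (-0.02) or the second at 6 h (0.08), and without the WT arrays marked Rep (0.02, adjusted p = 0.068). Early receptor response genes had medians of -0.22 and -0.21 (adjusted p = 8.6e-05 and 7.4e-05, adjusted p = 0.50 for both with an estimated correlation), with Fos at -0.59 and -0.75. Both medians subtract the same 0 h arrays, in which this list stood higher in transgenic cells. A weaker response cannot be told apart from that difference at 0 h, and both times are not separate evidence. The medians of this list were 0.04 and -0.05 without the WT arrays marked Rep, and -0.08 and -0.14 without the second WT array at 0 h alone. The 6 h call ended as well without the first transgenic array at 6 h (-0.14) or the second WT array at 6 h (-0.09). Cholesterol synthesis genes had medians of -0.09 and -0.20 (adjusted p = 0.023 and 5.0e-07, adjusted p = 0.67 and 0.38 with an estimated correlation), with Idi1 at -0.51 and -0.75 ± 0.18. Between genotypes Idi1 (10403413) read 0.48 at 0 h, -0.03 at 6 h and -0.26 at 24 h, so the 0 h arrays enter both values. The cholesterol call at 6 h ended without any of 4 arrays, the first transgenic or second WT array at 6 h (-0.02 and -0.03) or the second transgenic or WT array at 0 h (-0.05 and -0.04), and turned to 0.0105 (adjusted p = 0.50) without the WT arrays marked Rep.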

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

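In this part, the tests for a mislabelled array, neutrophil and monocyte content, the WT arrays marked Rep, gamma-delta T cells and the splits balanced for the mark Rep were chosen after the result was seen, whereas those on all splits, neuron markers and the neighbours of Nova1 were not.

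The response to stimulation differed between the genotypes in 13 tests of lists (camera, 4 at 6 h and 9 at 24 h), and no probe set passed a direct test (limma, 420 with an unadjusted p under 0.05 at 6 h and 625 at 24 h). At 6 h these were early T cell receptor response genes (median -0.22, -0.11 in the unmarked set and -0.31 in the set marked Rep), cytokines and chemokines (0.18, 0.08 and 0.20), Th17 genes (0.11, 0.20 and 0.07) and cholesterol synthesis (-0.093, -0.04 and -0.19). None of the 4 passed with an estimated correlation (adjusted p from 0.38 to 0.67). At 24 h, the medians were negative for early receptor response genes (-0.21, -0.13 and -0.34), ERK feedback genes (-0.21, -0.14 and -0.19), cholesterol synthesis (-0.20, -0.05 and -0.44), ribosome biogenesis (-0.17, -0.04 and -0.30), heat shock genes (-0.15, -0.07 and -0.08) and G1/S genes (-0.11, 0.12 and -0.40). The medians were positive for interferon-stimulated genes (0.48, 0.15 and 0.58), Th17 genes (0.44, 0.36 and 0.28) and cytokines and chemokines (0.14, 0.23 and -0.09). With an estimated correlation the adjusted p of these 9 ran from 0.38 to 0.84. The tests at 6 h and 24 h subtract the same 0 h arrays. A difference at 0 h therefore enters both, and a list called at both times is not called independently. Among the probe sets without a gene symbol, 1 (10545229) was higher in transgenic cells averaged over the times, by 1.81 (adjusted p = 0.025).

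Single arrays ended calls as well. At 24 h, the G1/S median turned to 0.18 and passed (adjusted p = 0.020) without the second transgenic array at 24 h, and was -0.08 and -0.01 without the second WT array at 0 h or the first at 24 h. The interferon call ended at 0.24 (adjusted p = 0.28) without the second transgenic array at 0 h, and ribosome biogenesis at -0.03 (adjusted p = 0.28) without the second WT array at 24 h. Heat shock genes ended at -0.08 and -0.05 without the first transgenic array at 0 h or the second at 24 h, at -0.13 and -0.11 without the second WT array at 0 h or 24 h, and at -0.12 without the WT arrays marked Rep. ERK feedback genes ended at -0.16 and -0.15 without the second transgenic or first WT array at 24 h. Early receptor genes ended at -0.14 without the second WT array at 0 h and at -0.05 without the WT arrays marked Rep. Cytokines ended at 0.07 without the second transgenic array at 24 h, turned to -0.14 without the first WT array at 24 h, and ended at 0.14 and 0.18 without the second transgenic or first WT array at 0 h. Without genes of more than 1 list cytokines were 0.03 and Th17 genes 0.06. At 6 h, cytokines ended at 0.19 and 0.18 without the second transgenic array at 6 h or the first WT array at 0 h, and at 0.09 without genes of more than 1 list. Early receptor genes turned to 0.04 without the WT arrays marked Rep and ended at -0.08, -0.09 and -0.14 without the second WT array at 0 h or 6 h or the first transgenic array at 6 h. Th17 genes ended at 0.02 without the WT arrays marked Rep, at -0.02 and 0.08 without the first transgenic array at 0 h or the second at 6 h, and at 0.06 without genes of more than 1 list. Cholesterol synthesis turned to 0.0105 without the WT arrays marked Rep and ended at -0.05 to -0.02 without the second transgenic or WT array at 0 h, the first transgenic or the second WT array at 6 h.

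Nova1 was higher in transgenic cells at every time. Ppp2ca was higher averaged over the times (0.57) and did not pass at 0, 6 or 24 h alone in the main fit (adjusted p = 0.055, 1 and 0.28). The smallest gap between the lowest transgenic and the highest WT array was 3.68 for Nova1. It tests no mislabelled array, since Nova1 stood out by separating the genotypes and a wrong label narrows a difference. Neurons in the samples were argued against by 11 neuron markers (median 0.014, none past the threshold). Of the 20 nearest tested genes 0 had an unadjusted p under 0.05, which argues against a differing stretch of chromosome that shifts several of them. A stretch that alters Nova1 alone was not tested. A transgene inserted near Nova1, or a transgene that carries part of it, stays open, since the labels give neither the insertion site nor the construct. A rise of Nova1 as a response to PP2Ac was not tested.

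Th17 genes had medians of 0.37 at 6 h, 0.72 at 24 h and 0.32 averaged over the times with 0 h included, and none of the 3 passed with an estimated correlation (adjusted p = 0.26 for each). That setting called no list in any comparison. At the preset correlation, neutrophil content as the whole cause of the average was argued against by 0.30 with the neutrophil marker level as covariate (adjusted p = 1.0e-09). Without the low WT arrays marked Rep the average stayed at 0.29. That left 1 WT array at each time, so the spread of WT cells was not measured and the part of those arrays is not settled. Gamma-delta T cells in the samples, which can make IL-17, cannot be told apart from a response of CD4 T cells, since only 3 of their markers were measured (median 0.062 at 0 h, adjusted p = 0.80). Monocyte content at 6 h cannot be told apart, since a lone WT array was left at 6 h without the WT arrays marked Rep. There monocyte markers were lower in transgenic cells (-0.20) and Th17 genes higher (0.30). Whether the marker shift passed depended on which arrays of the other times were kept. A response to the transgene stays open, as does the content of dendritic cells, whose markers were 0.25 for the mean of 3 times with the covariate (adjusted p = 4.3e-06).

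Interferon-stimulated genes had medians of 0.42, 0.55 and 0.87 at 0, 6 and 24 h and of 0.68 averaged over the times, none of which passed with an estimated correlation (adjusted p = 0.67, 0.47, 0.43 and 0.38). Without the WT arrays marked Rep the medians at the 3 times were 0.34, -0.23 and 0.80. The median at 6 h thus changed sign without those arrays, and those at 0 h and 24 h stayed positive. Since 1 WT array was left at each time, the spread of WT cells was not measured, and these values do not settle what the arrays contributed. At 0 h the median was 0.16 (adjusted p = 0.13) without the first transgenic array. The average was 0.47 (adjusted p = 2.5e-15) with the neutrophil marker level as covariate, which argues against neutrophil content as the whole cause. Monocyte content at 24 h cannot be told apart, since the marker median of -0.22 without the WT arrays marked Rep rests on a lone WT array, and dendritic cell content stays open. A response to the transgene, or a difference in interferon exposure between the mice or cultures, was not tested.

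For the genes differing between genotypes averaged over the times, chance cannot be excluded by the splits of the arrays within each time. Of 100 splits drawn from 108, 17 gave as many probe sets as the real 6, the highest other 1568, and 73 gave none. The split with 1568 follows the mark Rep, which points to a structure of the samples by that mark, and the count with the mark as a block was 18. Of the 29 splits with 1 array of each set in each genotype and time, 1, the real one, gave as many, and the highest other gave 2. Without Nova1 and Ppp2ca the real count was 3 and the highest other of these splits 0. Since 1 of 29 is the smallest share these splits could give, and the planned test on all splits gave 17 of 100, chance stays open for those 3.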

How the results depend on the processing

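Leaving out the 3 WT arrays marked Rep and the neutrophil marker covariate were tests chosen after the marker levels had been seen; all other alternatives were planned. With 2 arrays per group, leaving out 1 array leaves a lone array that is assumed to vary like the other groups. Of changes of 0.5 on the log2 scale simulated with independent noise, 38% were recovered at 1 time. A fit of only the compared groups gave no value for the mean of 3 times. Camera with an estimated correlation ended every list call, those of the responses to stimulation included. Where no construction is named below, the cause was not tested. With 1 probe set per gene, 1 gene differed at 0 h, 1 at 6 h and 1 at 24 h, since both calls at each time are probe sets of Nova1. Counts below are of probe sets. A fit of only the compared groups called 1 at 6 h and 1 at 24 h, from fewer arrays. With the block the counts were 4, 4 and 4, and 18 for the mean of 3 times. It also changed the calls of lists, adding 7 between genotypes, 5 of responses and 5 of their differences and ending 1, heat shock at 24 h in WT, and those of single genes given in the report; it moved no other count by over 1.5 times. The rotation test fry called 0, 1, 1 and 2 lists between genotypes at 0, 6 and 24 h and for the mean of 3 times, where camera called 16, 9, 14 and 18, and 0 differences of responses; of 168 list tests of responses, 14 gained and 14 lost a call. A minimum of 2-fold left 2 for the mean of 3 times by construction, and 1644 and 1355 of the WT and 1597 and 1153 of the transgenic responses at 6 h and 24 h. The covariate gave 17 for the mean of 3 times, and leaving out the WT arrays marked Rep 5 at 24 h and 2870 for the WT response at 24 h.

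Leaving out 1 array at a time gave 2 to 2 probe sets between genotypes at 0 h, 2 to 3 at 6 h, 2 to 6 at 24 h and 4 to 19 for the mean of 3 times, 4464 to 6110 and 4217 to 6226 for the WT responses at 6 h and 24 h, 4242 to 5942 and 3077 to 5498 for the transgenic ones, and 0 to 1 and 0 to 0 for the differences of responses.

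These turned in sign. Without the WT arrays marked Rep, between genotypes, neutrophil markers were -0.48, -0.55, -0.86 and, for the mean of 3 times, -0.68. Naive genes were 0.11 and FOXO targets 0.18 at 6 h and -0.0021 at 24 h, interferon-stimulated genes -0.23 at 6 h, ATF4 targets 0.35 at 6 h and 0.24 at 24 h, monocyte markers -0.20, -0.22 and -0.14 at 6 h, 24 h and the mean, antigen-experienced genes -0.14 at 24 h and G2/M genes -0.32 for the mean. Of the differences of responses, naive genes were 0.11, early receptor genes 0.043, FOXO targets 0.20 and interferon-stimulated genes -0.47 at 6 h, p53 targets 0.27 and B cell markers -0.20 at 24 h. Medians that lost their call and crossed 0 there were antigen-experienced genes (-0.025), G2/M genes (-0.0071) and inhibitory receptors (-0.028) at 0 h, chemokine receptors at 24 h (-0.0065), regulatory T cell genes for the mean (-0.0090) and cholesterol synthesis in the difference of 6 h responses (0.0105). Ppbp in WT at 24 h was 1.19. With the covariate G2/M genes at 0 h were -0.059.

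Leaving out 1 array at a time turned the following, given as the range over the 12 arrays. Between genotypes, these were neutrophil markers at 0 h (-0.48 to 2.85), naive genes (-0.17 to 0.11), FOXO targets (-0.31 to 0.18), interferon-stimulated genes (-0.23 to 1.41), ATF4 targets (-0.43 to 0.41) and monocyte markers (-0.20 to 1.58) at 6 h. At 24 h they were antigen-experienced genes (-0.14 to 0.44), G1/S genes (-0.49 to 0.16, and -0.15 to 0.061 for the mean of 3 times), G2/M genes (-1.02 to 0.96), histones (-0.90 to 0.91), ATF4 targets (-0.49 to 0.24), monocyte markers (-0.22 to 1.65) and platelet markers (-0.75 to 0.54). Of the differences of responses, they were naive genes (-0.16 to 0.15), FOXO targets (-0.31 to 0.24), interferon-stimulated genes (-0.64 to 0.92), monocyte markers (-0.92 to 0.82) and neutrophil markers (-2.01 to 1.43) at 6 h, and antigen-experienced genes (-0.18 to 0.35), cytokines (-0.14 to 0.35), G1/S genes (-0.48 to 0.18), G2/M genes (-1.31 to 0.70), B cell markers (-0.18 to 0.51) and monocyte markers (-0.89 to 0.86) at 24 h. Called medians also crossed 0 without the second WT array at 0 h (antigen-experienced genes -0.025, G2/M genes -0.0071 and inhibitory receptors -0.028 at 0 h) or 24 h (FOXO targets -0.0021 and chemokine receptors -0.0065), the second transgenic array at 0 h (Th2 genes at 0 h, -0.023), the first (Th17 genes in the difference of 6 h responses, -0.018), and the second transgenic or first WT array at 6 h (dendritic cell markers, -0.11 and -0.04). Ppbp in WT at 24 h ran from -1.17 to 1.12.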

Other observations

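Subunits and regulators of PP2A other than the transgene product changed with stimulation in WT cells. At 6 h Ppp2r5c (10398461) and Ppp2r5b, genes of B56 regulatory subunits, fell (-0.82 ± 0.07 and -0.97 ± 0.12; the other Ppp2r5c probe sets read -0.34, -0.42 and -0.53), and Ppp2r1b, the gene of the beta scaffold subunit, and Set, an inhibitor of the phosphatase, rose (0.75 ± 0.11 and 1.08 ± 0.17, with 0.60 in the other Set probe set). Of the 25 members 4 rose and 4 fell, 7 and 4 adjusted over the list alone, and the median was -0.04 with a mean of 0.03. At 24 h Lcmt1, which methylates the catalytic subunit, rose by 0.65 ± 0.09 and Ptpa, an activator of the phosphatase, by 0.46 ± 0.10 (limma, adjusted p = 0.00099 and 0.0065). In transgenic cells these values were 0.66 ± 0.09 and 0.42 ± 0.10.

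The machinery of DNA methylation moved in both directions. In WT cells Tet1 and Tet3, which oxidise methylcytosine, fell at 6 h (-1.87 ± 0.13 and -1.08 ± 0.10), and Dnmt1 fell at 6 h (-0.52 ± 0.11) and rose at 24 h (1.12 ± 0.11) together with Uhrf1, its partner at replicated DNA (3.38 ± 0.34). Transgenic cells had -2.12 for Tet1 at 6 h and 1.03 ± 0.11 for Dnmt1 and 3.28 for Uhrf1 at 24 h. The list's median at 24 h in WT was -0.14 with a mean of 0.28, and it did not pass (camera adjusted p = 0.59). Among survival and signalling genes in WT at 6 h, Bcl2l1, which encodes BCL-XL, rose by 1.97 ± 0.18. Ppp3ca, a calcineurin catalytic subunit (-1.45 ± 0.15), Nfatc2 (-1.03 ± 0.10), Cdkn1b, an inhibitor of cyclin-dependent kinases (-1.50 ± 0.15), and Sesn1, a stress-induced inhibitor of mTORC1 (-1.97 ± 0.17), fell.

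Markers of cells other than CD4 T cells fell after 24 h in transgenic cells for dendritic cells (4 of 7, 7 adjusted over the list alone, median -0.80, adjusted p = 0.00081, and adjusted p = 0.38 with an estimated correlation). The CD8 T cell markers had a median of 1.14 there (adjusted p = 0.094, and 0.020 with the block), with Cd8a at 1.88 ± 0.55. Replication-dependent histone genes had medians of 1.57 in the unmarked set and 0.54 in the set marked Rep in WT at 24 h, and 1.54 and -0.03 in transgenic cells, and did not pass (adjusted p = 0.13 and 0.28). The genes of cytosolic ribosomal proteins, 19 in number, did not move in WT at 6 h (0 up, 0 down, median -0.05, adjusted p = 0.39).

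Probe sets without a gene symbol also responded to stimulation. Of 5443, 329 rose and 176 fell at 6 h in WT and 264 and 192 in transgenic cells, and at 24 h 328 and 329 in WT and 221 and 290 in transgenic cells. Whether both genotypes came from the same C57BL/6 substrain, which bears on Nnt, was not tested.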
